A study of Mus musculus with 10 samples.

How the data were processed

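Total RNA was taken from whole skin of 5 vehicle and 5 quinpirole samples of imiquimod-treated mice, ribosomal RNA was depleted and directional libraries were made with MGIEasy kits, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.38, Bowtie2, RSEM 1.3.0, edgeR and the build mm10, with no role or order. The annotation, the filter on genes and the kind of normalisation factor are not given in the sources used here. RSEM can divide reads between near-identical genes, so members of families such as Sprr2, Krt6, Serpinb3 and Stfa are uncertain.

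The authors deposited a signal table of normalised values, with 17016 gene symbols and 10 libraries. In each column 100% of values were whole multiples of the smallest value, within 1e-06 of a read, so the reads behind them could be recovered. Recovered reads per library were 7859925, 6768604, 7361559, 7796398 and 7518384 in vehicle replicates 1 to 5, and 7728883, 6763367, 7611441, 8361877 and 7790385 in quinpirole replicates 1 to 5. A factor computed with edgeR's TMM method on these reads equalled the factor implied by the column total, within 2.22e-16, in each library. The values therefore equal CPM on TMM effective library sizes. No gene in the table had fewer than 10 reads in all, which leaves open what was removed below that. Of rows with more than 50 reads, 17 in 8 sets held identical values in all libraries. All value columns were mapped to samples by their labels.

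Values were divided by the mean column total on the CPM scale, the same constant for each library, and transformed as log2 of the value plus 1. A gene was tested if it reached 1 CPM in at least 5 libraries, which left 14548 genes. The test was limma 3.58.1 with a mean-variance trend, two-sided, without covariates, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Of 35 gene lists fixed before the data were examined, 33 had at least 5 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, by its directional test unless stated. An exact permutation test of the list mean was run over each split of the libraries into 5 and 5. The smallest p this allows is 0.00794. Intervals of list means and family sums invert the exact permutation test.

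The genes named were fixed before the data were examined as the dopamine receptors, 12 core psoriasis genes, and the 15 largest changes per direction among called genes, or the 10 smallest p where fewer than 5 were called, leaving out pseudogenes and provisional symbols. Up to 4 members with the smallest p in each called list were added. Genes named outside this rule, chosen after their values were seen, are Chil3, Defb3, Lcn2, Krt17, Sprr2a1, Per2, Arntl, Clock, the Skint, Gstm and Krtap genes, and Wnt5a, Peg3, Crip1, Mpc1 and Sprr2h. Positions came from the GENCODE annotation of the same build, in which 95.9% of the symbols matched a single gene.

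The same steps were tested on simulated data, 5 sets of negative binomial counts for 14548 genes with 200 changed genes in the comparison of quinpirole with vehicle. Limma called 67.8% of genes changed 2-fold and 93.6% of those changed 4-fold, with 6.14% of calls on unchanged genes. With no change simulated, at most 1 gene and 0 lists were called. These simulations hold no correlation between genes, which the real libraries do. Alternatives covered pseudocounts of 0.1 and 5, filters, scaling, variance models, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, tissue list means as covariates, and leaving out each library. These were fixed before the data were examined. Further alternatives, with the hair covariate under edgeR, camera or fry and without both libraries numbered 4, were added after. Pairs of libraries in a group differed by at least 6.22 in chi-square per gene, where sampling noise gives about 1, so none was a repeat of another. No batch labels were used here. Figures were drawn with matplotlib 3.10.9.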

Results

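RNA was sequenced from whole skin of female BALB/c mice aged 10 to 11 weeks in which skin inflammation resembling psoriasis was induced with imiquimod, an agonist of the innate immune receptor TLR7. A 5% imiquimod cream was put on the shaved back each day for 5 days. Quinpirole, an agonist of the dopamine receptor DRD2, was injected into the peritoneum 5 times over the same period in one group, and the other group received vehicle. There were 5 libraries per group. Reads assigned to genes ranged from 6763367 in quinpirole replicate 2 to 8361877 in quinpirole replicate 4. At this depth, 1 read was worth between 0.119 and 0.146 normalised CPM, a count scaled to the size of its library. Skin without imiquimod was not analysed here, so the comparison asks how skin under imiquimod differed with and without quinpirole, and not whether a level moved toward that of normal skin. The labels number the samples within each group and do not say that each came from a separate mouse, so p-values measure the spread between these samples.

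The libraries differed most in the genes of the hair shaft, and this difference ran across both groups. The first principal component of 14548 tested genes held 47.7% of the variance. Its score followed the mean log2 level of 44 hair keratin and hair shaft genes over the 10 libraries, with Pearson's r = 0.99 (permutation p = 4.00e-05) and Spearman's rho = 0.93 (permutation p = 3.00e-04), and r was 0.98 without the 2 libraries farthest from the median. This was the single relation of this kind computed. The 44 genes are themselves among the 14548, so part of the relation is built in, which the permutation p does not take into account. The hair list mean was 5.24, 6.03, 6.26, 3.32 and 0.64 in vehicle replicates 1 to 5, and 6.28, 0.76, 3.93, 0.72 and 2.67 in quinpirole replicates 1 to 5. The second component held 13.7% of the variance and differed between the groups with an exact two-sided permutation p of 0.0159, or 0.0794 after Benjamini-Hochberg adjustment over 5 components.

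**Figure D1:**
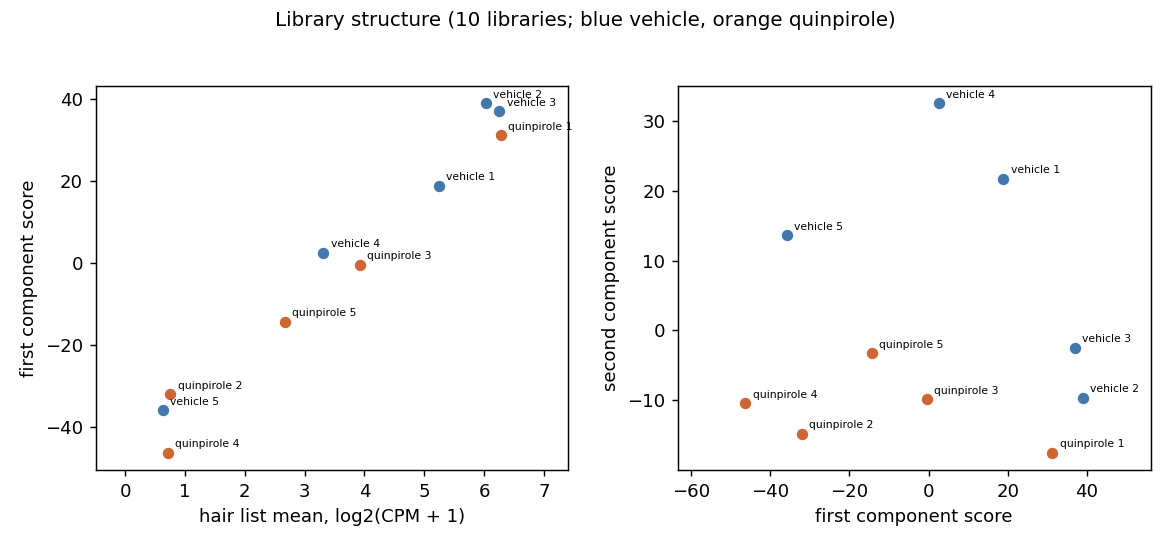
Left, the first principal component score of each library against the mean of 44 hair shaft genes, in log2 of CPM plus 1; right, the first and second component scores. Each point is 1 of 10 libraries, and libraries of both groups lie along the whole of the first component, with a hair list mean from 0.64 in vehicle replicate 5 to 6.28 in quinpirole replicate 1.

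Quinpirole is an agonist of DRD2. Drd1, which encodes another dopamine receptor, was listed at the edge of detection. It had 18 reads over the 5 vehicle libraries and 12 over the 5 quinpirole libraries, or 0.479 ± 0.0979 and 0.314 ± 0.067 CPM (SD, n = 5 each). Drd1 was below the filter for testing. With 2 to 5 reads per library its exact two-sided permutation p of 0.00794 (0.0159 adjusted over the 2 genes below the filter), the smallest that 5 against 5 libraries can give, rests on single reads. Drd2, Drd3, Drd4 and Drd5 were looked for and were not among the 17016 gene symbols of the authors' values. Their RNA could not be compared, and the sources used here do not say why they are missing. A list of 20 tested genes of dopamine signalling and metabolism had a median log2 fold change of 0.02 and was not called (camera adjusted p = 0.526).

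Single genes that passed the test between quinpirole and vehicle were few. Igfbp5, which encodes a binding protein of insulin-like growth factors, rose from 97.8 ± 15.5 to 207.0 ± 31.0 CPM (SD, n = 5 each), a log2 fold change of 1.08 with SE 0.13 (limma adjusted p = 0.0341). Dbp, a transcription factor driven by the circadian clock, rose from 6.40 ± 1.29 to 17.8 ± 4.86 (log2 fold change 1.33, SE 0.18, limma adjusted p = 0.0441). Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis and glyceroneogenesis, fell from 30.5 ± 10.7 to 7.41 ± 2.17 (log2 fold change -1.88, SE 0.25, limma adjusted p = 0.0441). For each of these genes the groups did not overlap. Fold changes are on the scale of log2 of CPM plus 1, which understates changes of low genes. On mm10, Igfbp5 is a protein-coding gene on the minus strand of chromosome 1, from 72857932 to 72874884. Dbp lies on the plus strand of chromosome 7 from 45705088 to 45710203, and Pck1 on the plus strand of chromosome 2 from 173153048 to 173159273.

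In all, 3 of 14548 genes were called by limma, 2 higher and 1 lower, against 1657 at an unadjusted p under 0.05, of which 1006 were higher. The groups did not overlap for 320 genes, 2.20% of those tested, where chance gives 0.794%. The count depended on the test: edgeR's quasi-likelihood test on recovered reads called 1 gene and DESeq2 called 219. Leaving out single libraries moved the count between 0 and 10, and limma called 0 genes without any 1 of 8 libraries (vehicle replicates 1, 2 and 4 and each quinpirole replicate), with 1319 to 2012 genes at an unadjusted p under 0.05.

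None of the following genes, which had the next smallest p in each direction apart from a pseudogene, passed the threshold. Sprr2i, a small proline-rich protein of the cornified envelope, measured 172 ± 65.9 in vehicle and 32.1 ± 14.5 with quinpirole (log2 fold change -2.42, limma adjusted p = 0.0505). The serine protease gene Tmprss11b had a log2 fold change of -2.41 (limma adjusted p = 0.0527), its relative Tmprss11g -1.01 (0.0807), the antimicrobial S100a7a -2.11 (0.0839), Sprr2f -1.85 (0.113), the tetraspanin Tspan3 -0.70 (0.121) and the kallikrein Klk13 -1.12 (0.142). Cdc20, an activator of the anaphase-promoting complex, had a log2 fold change of -0.61 (limma adjusted p = 0.0721). Pdcd1, which encodes PD-1, a receptor carried by T cells, had -1.13 (0.0721). On the higher side stood Emp3 at 0.65, Fam57b at 1.11, the fructose transporter Slc2a5 at 1.01, the aquaporin Aqp11 at 1.04 and the secretogranin Scg3 at 1.26, each with a limma adjusted p of 0.0721. The sodium channel gene Scn2a1 stood at 1.26 (limma adjusted p = 0.0781), the galectin Lgals1 at 0.58 (0.104) and Npl, a lyase of sialic acid breakdown, at 0.83 (0.105). Aqp11 averaged 0.436 CPM in vehicle and Pdcd1 0.608 with quinpirole, which is a few reads per library. By edgeR their log2 fold changes were 2.14 and -2.05, so the size of their change depends on how low values are handled. Sprr2i and Sprr2f share near-identical sequence with other Sprr2 genes, and their levels are uncertain where reads were divided among them.

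**Figure D2:**
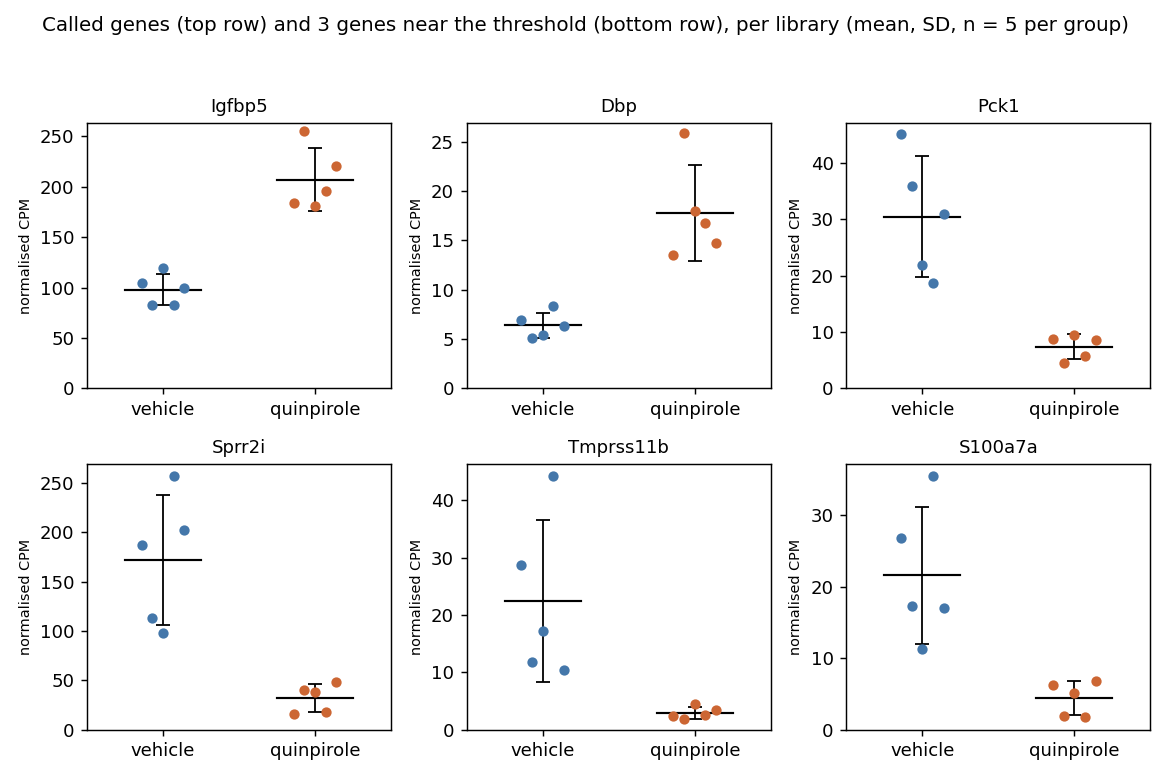
Normalised CPM in each library for Igfbp5, Dbp, Pck1, Sprr2i, Tmprss11b and S100a7a, on linear axes from 0; points are libraries, bars the mean and SD (n = 5 per group). The groups do not overlap for any of these 6 genes, of which Igfbp5, Dbp and Pck1 passed the adjusted threshold.

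The comparison next concerned the cytokines that drive psoriasis-like inflammation. None of those tested was called. The T cell cytokine Il17a measured 5.64 ± 3.42 in vehicle and 5.99 ± 5.81 with quinpirole (SD, n = 5 each; log2 fold change -0.05, 95% interval -1.06 to 0.97), Il17f 9.22 ± 7.10 and 9.17 ± 7.84, and Il23a 3.38 ± 1.34 and 3.13 ± 1.41. Quinpirole replicate 4 was far above its group for both of the first 2, at 16.3 for Il17a against 2.38 to 4.52 in the other 4 quinpirole libraries. Without it the quinpirole mean was 3.42 for Il17a (log2 fold change -0.45, limma adjusted p = 0.689) and 5.80 for Il17f (-0.41, 0.787). Vehicle replicate 1 was the highest of its group for both, at 21.1 for Il17f against 2.56 to 9.11 in the other vehicle libraries. Without vehicle replicate 1 the log2 fold change was 0.19 for Il17a and 0.31 for Il17f, so the sign depended on the library left out. The sign for Il17a turned in 7 of 27 alternatives, with log2 fold changes from -0.67 to 0.19. The interval is wide, and a change of up to about 2-fold in Il17a in either direction was not excluded. Il1b was 86.6 ± 97.3 in vehicle and 32.2 ± 11.3 with quinpirole (log2 fold change -0.85, limma adjusted p = 0.604). The vehicle mean of Il1b rested on vehicle replicate 4, at 256 against 17.4 to 77.4 in the other 4, and was 44.3 without it (log2 fold change -0.31, limma adjusted p = 0.829). Tnf had a log2 fold change of 0.26 (limma adjusted p = 0.625) and Il6 0.15 (0.905), or -0.11 for Il6 without quinpirole replicate 4 (0.917). Without vehicle replicate 4, the highest vehicle library for Il6, its log2 fold change was 0.38. Over 28 alternatives the value for Tnf lay between 0.12, without vehicle replicate 2, and 0.32. Il22 was below the filter, with 40 reads over the vehicle libraries and 10 over the quinpirole libraries (exact two-sided permutation p = 0.0159 unadjusted, and the same after Benjamini-Hochberg adjustment over the 2 genes below the filter). Tested without the filter, Il22 had a log2 fold change of -0.64 and a limma adjusted p of 0.297. The list of 17 tested genes of the IL-23 and IL-17 axis was not called (median -0.03 but mean 0.05, camera adjusted p = 0.672), and its median lay between -0.18 and 0.098 over 27 alternatives, none of which called it. The list of inflammatory cytokines was not called either (17 tested, 11 lower, median -0.18, camera adjusted p = 0.113; 0.894 with an estimated correlation). It was called lower in 6 of 27 alternatives: with the hair list mean as a covariate in limma (median -0.35, camera adjusted p = 0.00103) or in edgeR (-0.33, 3.91e-04), with the muscle list mean as a covariate (-0.32, 0.00382), and without vehicle replicate 2 (-0.22, 0.0235), vehicle replicate 3 (-0.25, 0.0193) or quinpirole replicate 4 (-0.27, 0.0368).

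The list of keratinocyte and antimicrobial genes that IL-17 induces fell with quinpirole. Of 49 tested members, 38 had lower values, and the median log2 fold change was -0.44 (camera adjusted p = 9.15e-09). The adjusted p was 0.645 with an estimated correlation, and the list mean had an exact permutation p of 0.0476, or 0.393 adjusted over 33 lists. No member was called over all genes tested; adjusted over the list alone, 14 members were lower and 1, Chil3, was higher (limma adjusted p = 0.0448). The lower ones included S100a8 and S100a9, the subunits of calprotectin. S100a8 measured 4739 ± 1323 in vehicle and 2531 ± 1106 with quinpirole (log2 fold change -0.98, limma adjusted p over all genes 0.270), and S100a9 6485 ± 1911 and 3268 ± 1350 (-1.05, 0.260). The stress keratins Krt6a and Krt16 had log2 fold changes of -0.96 and -0.73 (0.292 and 0.342), and the defensin Defb3 -1.95 (0.174). Other members had smaller values beside their error, with Lcn2 at -0.44 (SE 0.37) and Krt17 at -0.13 (SE 0.22), and Sprr2a1 was among those with higher values, at 0.25 (SE 0.21). Sprr2a2 carried values identical to Sprr2a1 and is counted beside it among the 49. Neutrophils also express S100a8 and S100a9, and the list of neutrophil markers, which holds neither gene, had a median of -0.44 with 14 of 20 members lower (camera adjusted p = 0.0302; adjusted p = 0.778 with an estimated correlation, and 0.397 with the preset one without vehicle replicate 4).

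**Figure D3:**
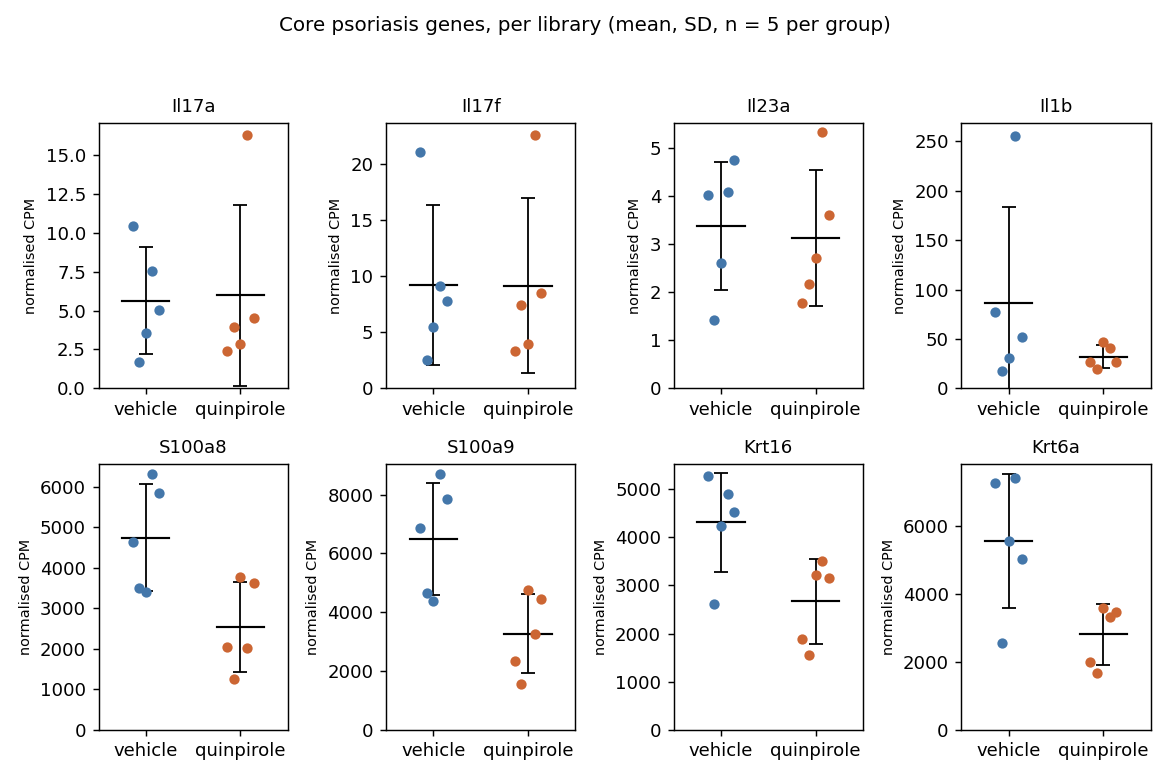
Normalised CPM in each library for the cytokines Il17a, Il17f, Il23a and Il1b and for S100a8, S100a9, Krt16 and Krt6a, members of the IL-17-induced list, on linear axes from 0; points are libraries, bars the mean and SD (n = 5 per group; the lower bar of Il1b in vehicle is cut at 0). Il17a averaged 5.64 in vehicle, or 4.45 without vehicle replicate 1, and 5.99 with quinpirole, or 3.42 without quinpirole replicate 4. Il1b averaged 86.6 in vehicle, or 44.3 without vehicle replicate 4. S100a8 averaged 4739 in vehicle and 2531 with quinpirole. None of the 8 genes passed the adjusted threshold.

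Other epidermal lists moved apart. The list of terminal differentiation rose (43 tested, 28 higher, median 0.24, camera adjusted p = 0.0158; adjusted p = 0.894 with an estimated correlation). Adjusted over the list alone, 15 members were higher and 5 lower, and none was called over all genes. The call was lost with the hair list mean as a covariate in limma (median 0.08, camera adjusted p = 0.485) or in edgeR (0.097, 0.412), with the muscle list mean as a covariate (0.02, 0.672), without both libraries numbered 4 (0.19, 0.0848), with quantile normalization (0.18, 0.0523), and without vehicle replicate 1 (0.18, 0.0593), vehicle replicate 3 (0.17, 0.0626), quinpirole replicate 3 (0.195, 0.139) or quinpirole replicate 4 (0.16, 0.0554); without quinpirole replicate 1 the median was 0.37. Within it the late cornified envelope genes went both ways: Lce1m had a log2 fold change of 1.63 (limma adjusted p = 0.159) and Lce3a -2.23 (0.169). The proliferation list fell (46 tested, 39 lower, median -0.24, camera adjusted p = 4.32e-07; adjusted p = 0.742 with an estimated correlation), with Cdc20 the member passing when adjusted over the list alone. Its median was -0.10 without quinpirole replicate 2 and, with the hair covariate, -0.14 in limma and -0.13 in edgeR, and it was called in each. Mki67 had a log2 fold change of -0.19 (limma adjusted p = 0.806), which was 0.0296 without quinpirole replicate 2 and -0.34 without vehicle replicate 5. The basal keratinocyte list was not called (median -0.02, camera adjusted p = 0.672).

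The circadian clock list rose, with 16 of 19 tested members higher and a median log2 fold change of 0.33 (camera adjusted p = 2.16e-06; adjusted p = 0.645 with an estimated correlation). Adjusted over the list alone, 8 members were higher and none lower, and Dbp was also called over all genes. Tef, which like Dbp is a PAR bZIP factor under clock control, had a log2 fold change of 0.61, the period genes Per2 and Per3 1.09 and 0.65, and Nr1d2, a repressor of the clock loop, 0.50. Their limma adjusted p over all genes lay between 0.182 and 0.235. The core activators had log2 fold changes of -0.14 with SE 0.16 for Arntl and 0.11 with SE 0.11 for Clock, and Nfil3, which opposes Dbp at its binding sites, had -0.39 with SE 0.17.

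**Figure D4:**
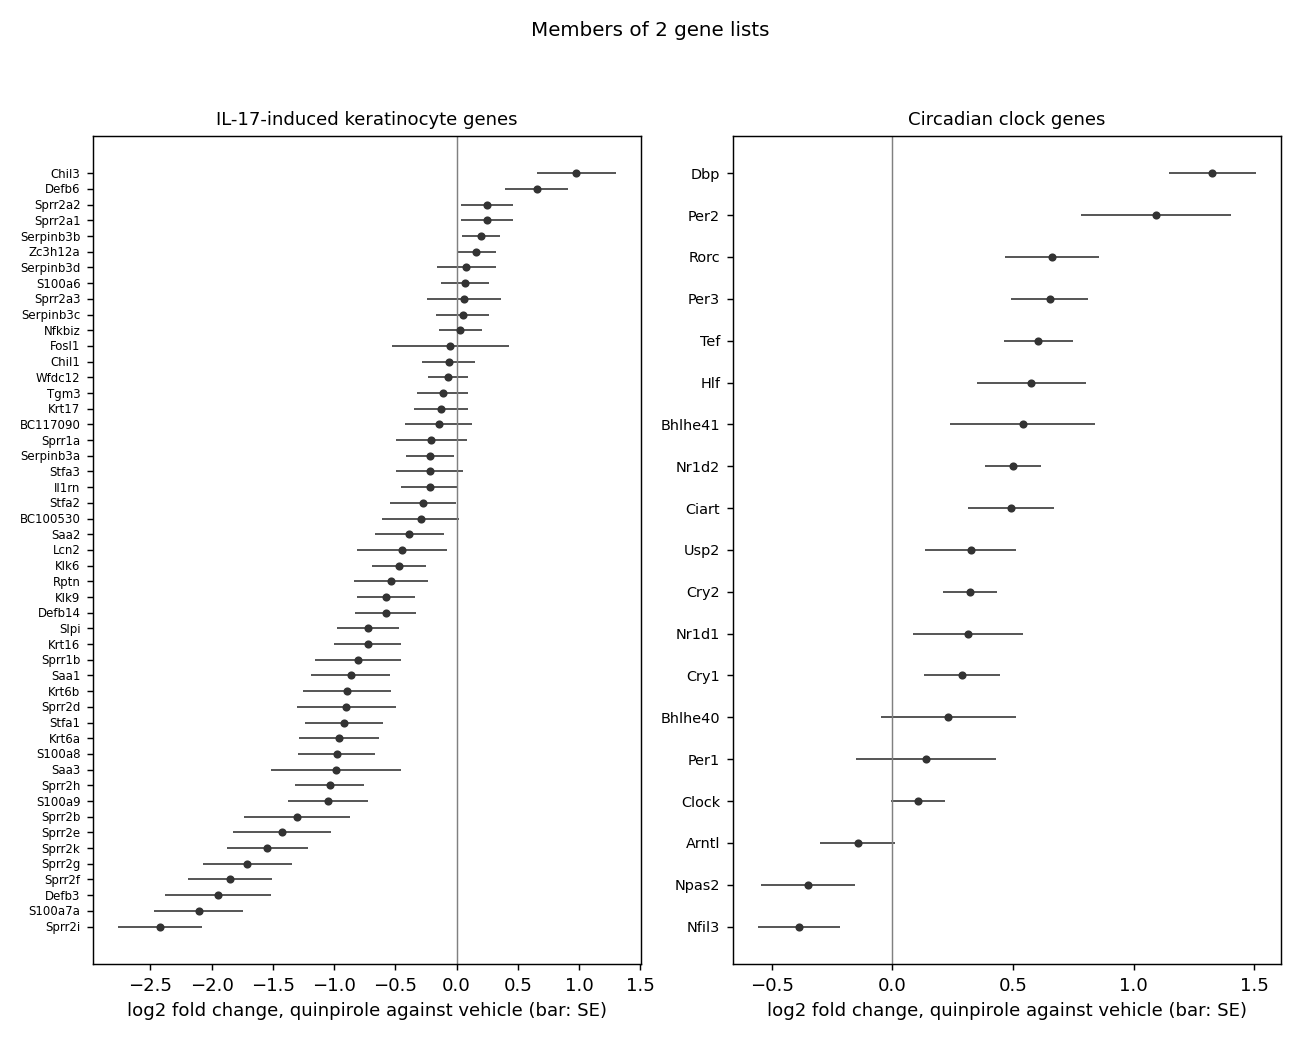
Log2 fold change, quinpirole against vehicle, of each tested member of the list of IL-17-induced keratinocyte genes (left, 49 genes) and of the circadian clock list (right, 19 genes); points are estimates and bars the SE from limma. In the left list 38 members lie below 0, and in the right list 16 lie above 0.

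Lists of skin appendages and of other tissue in the sample differed as well. The sebaceous gland and lipid synthesis list rose (29 tested, 22 higher, median 0.42, camera adjusted p = 4.40e-07; adjusted p = 0.645 with an estimated correlation), and 8 members were higher when adjusted over the list alone. Among them were the sebaceous duct keratin Krt79 (log2 fold change 0.73), the fatty acid elongase Elovl6 (0.93) and the hydroxylase Fa2h (1.19), with limma adjusted p between 0.169 and 0.178. The skeletal muscle list rose (35 tested, 32 higher, median 0.98, camera adjusted p = 3.70e-11; adjusted p = 0.645 with an estimated correlation), with Tcap at 1.40 and Myh1 at 1.51. Its mean was highest in quinpirole replicate 4, at 7.14 against 4.40 to 5.97 in the vehicle libraries, and without both libraries numbered 4, an alternative chosen after the data were examined, the median was 0.53. The hair shaft list fell (44 of 44 lower, median -1.55, camera adjusted p = 2.44e-06; adjusted p = 0.813 with an estimated correlation), and no member passed when adjusted over the list alone. Its median lay between -1.01 and -0.92 without vehicle replicate 3, quinpirole replicate 2 or quinpirole replicate 4, was -2.57 without vehicle replicate 5 and -2.53 without quinpirole replicate 1, and was -0.87 by edgeR. With the muscle covariate the call was lost (-0.0881, camera adjusted p = 0.711). The melanocyte list fell likewise (9 of 9 lower, median -0.93, camera adjusted p = 0.00581; adjusted p = 0.742 with an estimated correlation). That call was lost with the hair covariate in limma (median -0.11, camera adjusted p = 0.167) or edgeR (-0.15, 0.177) or the muscle covariate (-0.0435, 0.965), without both libraries numbered 4 (-0.62, 0.0658), and without vehicle replicate 2 (-0.56, 0.0648), vehicle replicate 3 (-0.55, 0.0506) or quinpirole replicate 4 (-0.53, 0.0725), and the median was -1.61 without vehicle replicate 5. With the muscle list mean as a covariate limma called 0 genes, with 1274 at an unadjusted p under 0.05, and with the hair list mean as a covariate 15 were called, 7 higher and 8 lower.

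Among immune cells, the mast cell list rose (15 tested, 11 higher, median 0.42, camera adjusted p = 0.00567; adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 6 members were higher and 1 lower. The mast cell proteases Mcpt4, Tpsab1 and Cpa3 had log2 fold changes of 0.81, 1.11 and 0.93, and Hs3st1, a heparan sulfate sulfotransferase, -1.29. The mast cell median was 0.28 without quinpirole replicate 2, 0.28 with the hair covariate and 0.21 with a pseudocount of 5, and the list was called in each. The interferon-gamma and antigen presentation list rose (27 tested, 24 higher, median 0.28, camera adjusted p = 3.46e-04; adjusted p = 0.742 with an estimated correlation), with B2m at 0.75 and the chemokine Cxcl9 at 0.96. Its call was lost without vehicle replicate 2 (median 0.17, camera adjusted p = 0.0587), and it was called at a median of 0.17 with the hair covariate in limma (0.00991) and in edgeR (0.00824). The type I interferon list rose too (42 tested, 36 higher, median 0.18, camera adjusted p = 0.00678; adjusted p = 0.815 with an estimated correlation) and the type 2 immunity list (11 tested, median 0.25, camera adjusted p = 0.0230; adjusted p = 0.645 with an estimated correlation). In the type I list, Zbp1 and Ifi204 had log2 fold changes of 0.77 and 0.53, but Rsad2 and Isg15 had -0.64 and -0.47. The limma adjusted p of these genes lay between 0.332 and 0.464. The type I call was lost with the hair covariate in limma (median 0.098, camera adjusted p = 0.109) and edgeR (0.11, 0.145) and without vehicle replicate 2 (0.07, 0.416). The type 2 call was lost with the hair covariate in limma (0.13, 0.150) and edgeR (0.11, 0.145), without both libraries numbered 4 (0.24, 0.0848), with the muscle covariate (0.04, 0.484) or array weights (0.19, 0.0505), and without vehicle replicate 2 (0.20, 0.101), vehicle replicate 3 (0.21, 0.0780) or quinpirole replicate 4 (0.18, 0.0725). The neutrophil list fell (20 tested, 14 lower, median -0.44, camera adjusted p = 0.0302; adjusted p = 0.778 with an estimated correlation), and so did the blood and erythroid list (10 tested, 8 lower, median -0.78, camera adjusted p = 0.00678; adjusted p = 0.645 with an estimated correlation). The neutrophil call was lost with a stricter filter of 5 CPM (median -0.32, camera adjusted p = 0.361) and without vehicle replicate 1 (-0.36, 0.0593), vehicle replicate 4 (-0.23, 0.397) or quinpirole replicate 1 (-0.40, 0.142), 2 (-0.34, 0.0777) or 3 (-0.30, 0.0535), and without both libraries numbered 4 (-0.22, 0.115). It was called at -0.28 with a pseudocount of 5 and at -0.83 by edgeR with the hair covariate. The blood and erythroid list was called without quinpirole replicate 3 and with no filter, at medians of -0.48 and -0.34. Of its members, Hbb-b2 and Hbb-bt carried identical values and cannot be counted as separate genes.

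Lists of glucocorticoid-responsive genes (20 tested, median -0.11, camera adjusted p = 0.0345) and of cAMP and CREB responsive genes (23 tested, median -0.10, camera adjusted p = 0.0466) also fell, with adjusted p of 0.645 and 0.713 with an estimated correlation. Pck1 is a member of the cAMP and CREB list and its only member that passed, over all genes or over the list alone. The list was not tested without Pck1. The glucocorticoid call was lost without vehicle replicate 5 (median -0.0144, camera adjusted p = 0.377) or quinpirole replicate 1 (-0.0239, 0.189), with the stricter filter (-0.08, 0.0686) and with array weights (-0.17, 0.152), and its median was -0.16 without vehicle replicate 1 and -0.23 without quinpirole replicate 4. It was called at a larger size with the hair covariate in limma (-0.24, 0.00144) and edgeR (-0.21, 6.16e-04), with the muscle covariate (-0.25, 8.77e-04) and without both libraries numbered 4 (-0.21, 0.0136). The cAMP and CREB call was lost without vehicle replicate 2 (0.0568), vehicle replicate 5 (0.362) or quinpirole replicate 1 (0.230), 2 (0.0680), 3 (0.0574) or 5 (0.0883), the p in brackets being camera's adjusted p, and with a pseudocount of 5 (0.0541), no filter (0.0510) or quantile normalization (0.0522); its medians without single libraries lay between -0.17 without vehicle replicate 1 and -0.0278 without quinpirole replicate 5. It too was called at a larger size with the hair covariate (-0.25, 0.00209), with the muscle covariate (-0.18, 0.00119) and without both libraries numbered 4 (-0.15, 0.00237). In total 16 of 33 lists were called by camera with the preset correlation, 8 higher and 8 lower, and 17 were not, with camera adjusted p from 0.0607 to 0.912. Of these 17, 11 were called in some alternative of the preset test. The T cell list (median -0.13, camera adjusted p = 0.220) was called lower in 6, among them the hair covariate (-0.21, 0.00860), and the list of NF-kB targets (-0.04, 0.568) in 4, among them the hair covariate (-0.11, 0.00794). The monocyte and macrophage list (0.12, 0.0607) was called higher in 8, among them leaving out vehicle replicate 1 (0.24, 0.00628), while its median was -0.03 without vehicle replicate 2. No list was called with an estimated correlation or by fry's directional test. The exact permutation test of the list mean called none either, with 4 lists at an unadjusted p under 0.05. Its smallest p of 0.00794 limits it by construction, as several lists would have to reach it for any to pass. Fry's mixed test, which lets members go either way, had an adjusted p under 0.05 for some lists. Among these were the clock list (0.00624) and the IL-17-induced list (0.0177), while the muscle list had 0.108. The adipocyte (0.00585), oxidative stress (0.0252), Schwann cell (0.0362) and chemokine (0.0493) lists passed too, though camera did not call them. Passing the mixed test was thus not particular to the lists that camera called. Of 100 splits of the 10 libraries, 29 called at least as many lists as the split into vehicle and quinpirole.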

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

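The tests of explanations given here were chosen after the results were seen, except the counts of other splits, which were planned before their outcome was known. The rules of the Sprr2, keratinocyte share and single library tests were changed after their first outcomes were seen. Over 93 named genes and 33 lists, each in both groups of 5 libraries, 14 groups held a library whose gap to its nearest neighbour took an unusually large share of the group's range. Chance alone flags about 1 in 20 groups, so this number is close to what chance gives.

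Quinpirole replicate 2 stood apart for Mki67 (gap 0.808 of the range), Lce1m (0.877), Ccl24 (0.715) and Per3 (0.831). Quinpirole replicate 4 stood apart for Il6 (0.827) and B2m (0.738). Vehicle replicate 5 stood apart for Mki67 (0.727), Ccl24 (0.796), Retn (0.891) and the list of glucocorticoid-responsive genes (0.734). Vehicle replicate 2 stood apart for Pdcd1 (0.7495) and vehicle replicate 1 for Angptl4 (0.739). Quinpirole replicate 3 had a low mean of the blood and erythroid list (0.7495), and quinpirole replicate 1 a low mean of the oxidative stress list (0.810).

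The first pattern is the lower list of IL-17-induced keratinocyte genes beside Il17a, Il17f and Il23a values that did not pass any test, and beside lower Il22, with 40 reads in vehicle and 10 with quinpirole (exact permutation p = 0.0159, also when adjusted over the 2 genes below the filter; limma adjusted p = 0.297 without the filter). The hair cycle stage is argued against, since the 38 members outside Sprr2 had a median of -0.28 and, with the hair list mean as a covariate, -0.43. Fewer keratinocytes stay open: the interval of the basal keratinocyte list mean had a lower bound of -0.16, but the members of that list went both ways, from -0.54 to 0.60 with an SD of 0.31, which is wider than the -0.28 to be explained. For the Sprr2 members, reads shared between copies stay open. The sum over 11 Sprr2 genes, with identical rows taken once, differed by -0.43 on the log2 scale (interval -1.02 to 0.19, exact permutation p = 0.135). The interval holds both 0 and the -0.58 expected if the lower members fell and the others stayed level, so the explanations cannot be told apart. An action of quinpirole stays open as a hypothesis for the other members, and so does, for S100a8 and S100a9, which neutrophils also express, a lower content of these cells, with the neutrophil list at a median of -0.44.

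The second pattern is the higher skeletal muscle list. Its members moved together within groups, with a mean correlation of 0.730, and 32 of 35 were higher, as would be seen if the samples held different amounts of the muscle under the skin; a muscle gene programme that changed as a whole might look alike. Quinpirole replicate 4 adds to the pattern, but it is argued against as the sole source, since without it the median log2 fold change was 0.72 in place of 0.98 and the list was still called (camera adjusted p = 2.02e-07 at the preset correlation). The exact permutation p of the list mean was 0.103 with that library and 0.167 without it, so a difference between the groups is not shown by that test.

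The third pattern is the higher circadian clock list. With the hair list mean as a covariate its median was 0.31 against 0.33, which argues against the hair cycle stage as the whole cause. Time of day at sampling could give it, and the labels used here give no time. Arntl, which peaks opposite to Dbp, had a log2 fold change of -0.14 (limma 95% interval -0.48 to 0.20), which neither shows nor excludes a shift of phase, so the time of sampling and the treatment cannot be told apart for this list.

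Other splits of the 10 libraries bear on the counts. Of 100 splits, 4 called at least as many genes as the real one, the real one included, a share under 0.05 by a small margin. The other 3 each called more genes than the real one. Several counts were compared in this way without adjustment, so chance is not excluded for this count. The share concerns the count and not the single genes called. The highest other split called 882 genes, which points to a structure of the samples. For lists, 29 of 100 splits called as many as the real 16, with a highest other count of 24, so chance is not excluded. With the hair covariate, 2 of 100 splits called as many as the real 15, the real one included, and the highest other split also called 15. This share is under 0.05, but it too was not adjusted over the several counts compared, so chance is not excluded for that count. Of the tissue covariates, only the hair list mean was run on other splits. In the real split the skeletal muscle covariate called 0 genes and the adipocyte covariate 3. By DESeq2 on the recovered reads, 3 of 40 splits called as many as the real 219, with a highest other count of 1409, so chance is not excluded for that count.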

How the results depend on the processing

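Alternatives with the hair covariate under edgeR, camera or fry, and without both libraries numbered 4, were chosen after the data were examined. The cause of the changes was not tested unless stated. Igfbp5, Dbp and Pck1 kept their direction in each of the 28 alternatives run on them, with log2 fold changes from 0.998 to 1.15, 0.98 to 1.47 and -2.04 to -1.48, and passed the threshold in 17, 15 and 15 of them. The 3 genes called became 5 with a pseudocount of 0.1 (2 higher, 3 lower), 4 with a pseudocount of 5 (2 lower), 6 with no filter (3 lower), 5 with a stricter filter (3 lower), 5 with median of ratios (3 lower), 5 with the same column total (3 lower), 4 with quantile normalization (2 lower), 9 with limma without trend (5 higher, 4 lower) and 21 with array weights (15 higher, 6 lower). The counts were 1 by edgeR (1 higher, 0 lower), 219 by DESeq2 (150 higher, 69 lower), 15 with the hair follicle covariate (7 higher, 8 lower), 0 with the skeletal muscle covariate (0 higher, 0 lower), 13 by edgeR with the hair covariate (6 higher, 7 lower) and 0 by limma without both libraries numbered 4 (0 higher, 0 lower; 1453 at an unadjusted p under 0.05). They were 15 at an adjusted p under 0.1, 146 at an unadjusted p under 0.05 with a 2-fold change, and 0 by the exact Wilcoxon test, whose smallest p of 0.00794 limits it by construction. Leaving out 1 library gave 0 to 10 genes (0 to 8 higher, 0 to 2 lower), with 1 without vehicle replicate 3 and 10 without vehicle replicate 5.

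The replicate number as a block gave 0 genes called by limma (0 higher, 0 lower; 1576 at an unadjusted p under 0.05), and 17 lists. The labels used here do not say whether the numbers pair the samples. Same-numbered libraries correlated at 0.22, -0.24, 0.19, 0.13 and 0.10, and not every library correlated best with its own number. The hair shaft genes varied widely within groups and enter these correlations, so they neither show nor exclude a pairing.

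The 16 lists called were between 13 and 18 under settings of the preset camera test, and 0 with an estimated correlation, 0 by fry, 0 by exact permutation of the list mean, and 0 by either of the first 2 with the hair covariate. DESeq2 gave no list test. Among lists called before or after the change, the direction given by camera turned for the hair list by edgeR with the hair covariate (median 0.0338, not called) and, with the muscle covariate, for fibroblast (median from -0.09 to 0.15), hypoxia (from 0.09 to -0.16) and melanocyte, whose median kept its sign (-0.0435, not called). The medians of the muscle list with its own mean as covariate (-0.00361) and of the hair list with its own (-0.0330) were near 0 by construction. For 11 lists called neither before nor after, the direction given by camera turned 49 times, 5 of them with the hair covariate in limma (the IL-23 and IL-17 axis, dendritic cell, immediate-early and oxidative stress lists to lower, fibroblast to higher). The first component held 71.6% of the variance over the 500 most variable genes. Depth limits low genes: Il22 and Drd1 rest on 1 to 16 reads per library. Aqp11 in vehicle and Pdcd1 with quinpirole also rest on few reads.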

Other observations

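Families of genes sharing a symbol stem were compared after the data were seen, over 437 families with at least 5 tested members, with camera at the preset correlation. Stems were taken up to the first digit, except that Sprr2, Tmprss11 and Pla2g4 were set apart after their members' values were seen. In all 9 families were called, and none with an estimated correlation (adjusted p = 0.995 for each) or by exact permutation of the family mean (adjusted p of 0.267 or more). Over 437 families the smallest permutation p of 0.00794 limits that last test by construction, so its outcome says little. With stems up to the first digit throughout, 7 of 436 families were called, namely Adamts, Fxyd, Gstm, Krtap, Lce, Skint and Sprr. No family holding the Pla2g4 or Tmprss11 genes was among them. The Skint genes, which encode butyrophilin-like proteins of keratinocytes that shape epidermal gamma-delta T cells, were higher in 8 of 8 tested members (median log2 fold change 0.91, camera adjusted p = 1.26e-05), with Skint10 at 1.41 and Skint11 at 1.02. The Gstm glutathione transferases were higher in 5 of 6 members (median 0.36, camera adjusted p = 0.00430), with Gstm1 at 0.64. Leaving out single libraries, or adding the hair or muscle list mean as a covariate, kept the calls of Skint and Gstm, and also those of Sprr2 (8 of 11 lower, median -1.30, camera adjusted p = 1.26e-05) and Pla2g4 (5 of 6 lower, median -0.61, 0.00796). Sprr2a1 and Sprr2a2 carried identical values and are both counted among these 11. Because Sprr2 and Pla2g4 were set apart after their values were seen, keeping their calls is no separate evidence for them. The calls of the other families were each lost in some of these settings, with camera adjusted p in the ranges given: Adamts (14 of 17 lower, median -0.43, camera adjusted p = 0.00453) with either covariate and without vehicle replicate 2 or quinpirole replicate 4 (0.0672 to 0.473), Fxyd (6 of 6 higher, 0.41, 0.0223) with either covariate and without vehicle replicate 3 or quinpirole replicate 2 (0.0544 to 0.123), Tmprss11 (4 of 6 lower, -0.67, 0.0269) with the muscle covariate and without vehicle replicate 5 or quinpirole replicates 1, 2 or 4 (0.0521 to 0.0769) and Lce (15 of 21 higher, 0.74, 0.0336) with the hair covariate and without vehicle replicate 3 or quinpirole replicates 2, 3 or 5 (0.119 to 0.173). The hair keratin-associated Krtap genes, 13 of which are in the hair shaft list, were lower in 34 of 34 members (median -1.22, camera adjusted p = 0.00430). Like that list, whose mean ran from 0.64 to 6.28 across both groups, they varied between libraries within groups: the exact permutation p of the family mean was 0.405, and the median was 0.08 with the hair covariate. The Krtap call was lost with either covariate and without vehicle replicates 2 or 3 or quinpirole replicates 2 or 4 (camera adjusted p of 0.782 and 0.973 with the covariates and 0.157 to 0.194 without these libraries, where medians lay from -0.86 to -0.78), and the median was -1.91 without vehicle replicate 5 and -2.02 without quinpirole replicate 1.

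With the hair list mean as a covariate, 15 genes were called by limma. Beside Igfbp5, Dbp and Pck1 these were Sprr2i (log2 fold change -2.61), Sprr2f (-2.06), Sprr2h (-1.27), Tmprss11b (-2.34), Pdcd1 (-1.22), Peg3 (-0.92) and Wnt5a (-0.71) on the lower side, and Scg3 (1.09), Emp3 (0.67), Npl (0.71), Crip1 (0.58) and Mpc1 (0.65) on the higher side. Their limma adjusted p lay between 0.0289 and 0.0485. Over the 14548 genes tested, 1038 changed with the hair list mean in the same fit.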
